A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

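RNA-seq and ribosome profiling (RIBO-seq) libraries of BY4741 yeast were read from 1 table of 6016 protein-coding genes with a column per library. Per the labels' protocols, lysates were digested with RNase I, monosomes were taken by size exclusion, footprints of 25 to 33 nt were selected, and RNA-seq used rRNA-depleted RNA from an aliquot of the lysate. Reads were processed with cutadapt and STAR on build R64, per the submitters' processing notes, which give no versions. The counting tool, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited counts are whole reads per gene. The deposited RPKM values are per kilobase of coding length and scaled to a library total slightly above the sum of the counts. The deposited ratio (translational efficiency) equals the footprint RPKM plus 0.01 over the RNA RPKM plus 0.01 for 100% of values within 0.1 percent. Near-identical gene copies carried nearly the same counts (TEF1 362577 and TEF2 370540 reads in control RNA replicate 1), so values of close paralogs are uncertain. The 91 rows of transposon gag and gag-pol genes held 69.8 to 72.9% of summed RNA counts and 20.6 to 23.2% of summed footprint counts. The copies CUP1-1 and CUP1-2 had the same deposited ratio in every pair of libraries, as they would if a read were counted in each copy. Shares of the transposon rows and sums of counts may therefore exceed those of the reads sequenced. Values of overlapping or antisense genes are uncertain for the same reason. Locus tags of 6013 genes matched the R64 RefSeq gene table, and 6012 had the same start and end.

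Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05, two-sided). RNA and footprints were each tested in their own 4 libraries, the baseline ratio in the 4 control libraries, and the change of the ratio as an interaction over all 8 libraries. Adjusted p means the edgeR value, or for lists that of camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 38 lists of at least 3 tested members. That list test compares members with all other genes, so its p is not a measure of the spread between libraries. When the correlation is estimated per list, camera rests on the few residual degrees of freedom of the fit. A list could then hardly pass, so a high adjusted p with an estimated correlation is not evidence against it. The gene lists (39 written from textbook knowledge, 1 without any row), the design and the alternatives were chosen before the data were examined, apart from those named as added. Several lists share members: the Gcn4 list overlaps the arginine, leucine, methionine, vitamin B6 and stationary phase lists. DESeq2 1.42.0 and limma-voom served as alternatives, with other scalings, filters, blocks and leaving out each library in turn. SE is the log2 change divided by the square root of the test's F. Normalised CPM (counts scaled to library size) use TMM factors of the assay.

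Genes were named by a fixed rule: per comparison the 10 higher and 10 lower genes with the largest log2 change among those past the threshold, with a mean of at least 10 CPM and non-overlapping libraries (the 5 of each sign with the smallest p, as values, where fewer than 5 pass), the 4 members with the smallest p of each list described, and 13 fixed marker and machinery genes. Genes named outside it (AI4, AI5_ALPHA and COX1 from the blocked fit) were chosen after their values were seen. A gene that the rule takes is not reported here.

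RNA and footprint libraries of a number come from 1 lysate per the labels' protocols, and the authors' ratio columns pair them. Deviations of paired libraries from their group means correlated with r of 0.299 in control and 0.270 in targeted cells. The fit with the culture as a block was listed as an alternative before the data were examined. In the labels, control and targeted libraries share only a number, and a shared day or batch is not excluded. On simulated counts with 200 changed genes, 1.5-fold changes were recovered for 67 of 67 genes in RNA, 62 of 67 in footprints, 41 of 67 for the change of the ratio, and 62 of 67 for the baseline. The simulation gave every gene the median dispersion, changed only genes with many reads and drew libraries independently. Recovery in the data may therefore be lower. Groups of 2 allow no outlier test and no count of regrouped samples. The lists by stop codon and by AAG codon share were not run, since no coding sequences were used here. Reporter and guide RNA values were not analysed here.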

Results

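Ribosome footprints and mRNA were sequenced from haploid yeast, strain BY4741 of Saccharomyces cerevisiae, carrying an mCherry reporter gene with a premature UAG stop codon and a cassette that expresses guide RNAs for targeted pseudouridylation, the conversion of a chosen uridine to pseudouridine. In the targeted cells the guide RNAs addressed the premature stop codon of the reporter and the anticodon of a lysine tRNA, and the control cells carried control guide RNAs. The table held 8 libraries in 4 groups of 2, with RNA-seq and RIBO-seq of control and of targeted cells. Summed RNA-seq counts were 61908589 and 33911841 in control cells and 33947846 and 21073013 in targeted cells. Summed footprint counts were 11849950 and 8080039 in control cells and 15253540 and 14163627 in targeted cells. Replicates correlated across genes with Pearson r of at least 0.993 on log2 CPM (counts scaled to library size), and every replicate pair differed by more than sampling noise, with chi-square per degree of freedom from 5.29 to 18.4. The chi-square includes the transposon rows. In the control RNA pair, which had the 18.4, they held 72.4 and 69.8% of the summed counts, so part of it comes from them. The labels do not say whether replicates came from separate cultures, so p-values of genes measure the spread between these samples, which may be technical. List p-values with the preset correlation compare members with other genes instead. Very small ones are therefore not strong evidence from 2 samples per group.

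The markers LEU2, URA3 and HIS3 were read in every library. Whether URA3 and HIS3 reads came from the chromosome or from an introduced copy was not tested. LEU2, an enzyme of leucine synthesis that is deleted in the parent strain and commonly carried on plasmids, had 4096 ± 220 normalised RNA CPM in control cells and 2857 ± 269 in targeted cells (SD, n = 2), a log2 difference of -0.52 ± 0.10 (SE) with an edgeR adjusted p of 0.0971. Its footprints differed by -0.46 ± 0.11 with an edgeR adjusted p of 0.165. Without control replicate 2 LEU2 was called lower in RNA (-0.58, adjusted p of 0.0442), as it was with library size only (-0.59, 1.34e-14) and with at least 10 CPM in 2 libraries (-0.52, 0.0438), and without targeted replicate 2 in footprints (-0.58, 0.00318). DESeq2 placed both LEU2 differences past the threshold, with adjusted p of 3.15e-06 for RNA and 0.000131 for footprints. Without the transposon genes edgeR also called LEU2 lower in footprints (-0.46, adjusted p of 0.0214). URA3, of uracil synthesis, had RNA log2 -0.02 ± 0.07 and footprint log2 -0.35 ± 0.12, with adjusted p of 0.989 and 0.700. Its footprint value ranged from -0.57 to -0.15 with a library left out and was called lower without control replicate 1 (-0.43, adjusted p of 0.0401) or targeted replicate 1 (-0.57, 6.85e-15), and with the number as a block (-0.36, 0.00857). HIS3, of histidine synthesis, had RNA log2 0.35 ± 0.07 and footprint log2 0.35 ± 0.07, with adjusted p of 0.181 and 0.0686. Its footprints were called higher without targeted replicate 1 (0.33, adjusted p of 0.00547) or targeted replicate 2 (0.36, 0.0138), without a filter on low counts (0.35, 0.0450), with at least 10 CPM in 2 libraries (0.35, 0.0443) and with the number as a block (0.35, 0.00545). MET17, which is deleted in this strain, had 0 or 1 read in each of the 8 libraries.

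The first comparison asked which mRNAs differed between targeted and control cells. The largest called changes included genes of amino acid synthesis. ARG1, argininosuccinate synthase, went from 58.9 ± 3.68 to 106 ± 5.74 normalised CPM (SD, n = 2), a log2 change of 0.85 ± 0.07 (SE) or 1.80-fold. HIS4, an enzyme of histidine synthesis, rose by 0.76 ± 0.07, and both had an edgeR adjusted p of 0.00212. Of 5712 genes tested, 21 were called higher and 0 lower at a false discovery rate of 0.05, with 181 higher and 74 lower under an unadjusted p of 0.05 where 286 in all are expected by chance. DESeq2 called 28 higher and 2 lower, and limma-voom 22 higher and 0 lower. With library size as the only scaling, which moved the median of all genes by -0.07, the split was 15 higher and 2 lower. All calls ended without the control library of replicate 1, a fit with 1 control library whose spread comes from the targeted pair alone. In that fit ARG1, HIS4 and GCV2 were at 0.78, 0.74 and 0.73, against 0.85, 0.76 and 0.65 with all libraries. The loss of these calls therefore does not mean that their changes were made by that library. Without targeted replicate 1 there were 9 calls, without targeted replicate 2 there were 13, and without the transposon genes there were 13.

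Further genes called in RNA were taken by the naming rule. GCV2 and GCV1, subunits of the glycine cleavage complex, rose by 0.65 ± 0.08 and 0.58 ± 0.08. ARG7 and ARG4, of arginine synthesis, rose by 0.59 ± 0.06 and 0.52 ± 0.06, and SNZ1, of vitamin B6 synthesis, by 0.66 ± 0.08. YGL117W, a gene of unknown function, rose by 0.77 ± 0.12, and YHI9 by 0.54 ± 0.08. Their edgeR adjusted p ranged from 0.00681 for ARG7 to 0.0437 for YHI9. YHI9 lost its call whichever of the 4 libraries was left out (adjusted p from 0.0996 to 0.572) while its log2 change stayed at 0.51 to 0.56, and YGL117W kept it only without control replicate 2, with log2 changes from 0.62 to 0.91 over the 4 fits. Without transposon genes both had an adjusted p of 0.0506 (0.54 and 0.77), DESeq2 gave neither an adjusted p, and with library size only YHI9 was at 0.47 with 0.103. ARG4 lost its call without control replicate 2 (log2 0.51, adjusted p of 0.0790), SNZ1 without targeted replicate 1 (0.61, 0.115) and GCV1 without targeted replicate 2 (0.50, 0.0577), besides the loss of all calls without control replicate 1, where ARG7 was at 0.59, GCV1 at 0.61, ARG4 at 0.53 and SNZ1 at 0.56.

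Of the 46 tested members of the list of amino acid genes regulated by Gcn4, the transcription factor of amino acid starvation, 10 were called higher in RNA and 36 did not pass, and 43 of the 46 lay above 0. Their median log2 change was 0.29, and 36 passed when adjusted over the list alone. The list test gave an adjusted p of 3.47e-90 with the preset correlation, and adjusted p = 0.303 with an estimated correlation. All 11 members of the lysine list lay above 0 with a median of 0.13, with an adjusted p for the list of 1.05e-09 and adjusted p = 0.303 with an estimated correlation. LYS20, homocitrate synthase, was called at 0.38 ± 0.06 (adjusted p of 0.0437) and lost the call without control replicate 1 (log2 0.38, adjusted p of 0.743), control replicate 2 (0.38, 0.306) or targeted replicate 1 (0.36, 0.115), with library size only (0.31, 0.540), with the number as a block (0.38, 0.0530) and without transposon genes (0.38, 0.0506). The arginine and polyamine list (median 0.11) held ARG1, ARG4 and ARG56 as its 3 called members of 17, and its list p of 1.56e-11 became adjusted p = 0.303 with an estimated correlation. ARG56 lost its call without targeted replicate 1 (log2 0.47, adjusted p of 0.115). All 3 also belong to the Gcn4 list, and without Gcn4 members the list mean went from 0.18 to 0.0400 with an adjusted p of 0.374. The leucine and uracil list (median 0.09) had an adjusted p of 2.60e-05 and adjusted p = 0.476 with an estimated correlation, with no called member over all genes, and 0.192 without Gcn4 members. The methionine and sulfur list (median 0.14) had 8.17e-06 and adjusted p = 0.571 with an estimated correlation, while without control replicate 1 its mean went from 0.15 to 0.0848 with an adjusted p of 0.124. Subtelomeric and flocculation genes (median 0.33) had 0.000736 and adjusted p = 0.571 with an estimated correlation, while without targeted replicate 2 their mean went from 0.29 to 0.20 with an adjusted p of 0.0585. Thiamine and vitamin B6 genes were not called as a list (adjusted p of 0.467).

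The cytosolic ribosomal protein genes had a median RNA log2 of -0.07, with 134 of 137 members below 0 and none past the threshold. The list test called them lower with an adjusted p of 1.73e-08, and adjusted p = 0.897 with an estimated correlation, and without targeted replicate 2 the mean changed sign to 0.0119. Of the mitochondrial ribosomal proteins, 51 of 67 lay below 0 (median -0.05), with a list adjusted p of 0.00118 and adjusted p = 0.326 with an estimated correlation, and 0.0558 without targeted replicate 1, where the mean went from -0.0695 to -0.0761. Nuclear genes of oxidative phosphorylation (median -0.04) had 0.0386 and adjusted p = 0.513 with an estimated correlation, and lost the call without control replicate 1 (mean -0.0341, adjusted p of 0.227), targeted replicate 1 (-0.0529, 0.155) or targeted replicate 2 (-0.0378, 0.0632), against a mean of -0.0411 with all libraries. The genes of pheromone response in haploid MATa cells had a median of -0.08, with AGA1, an agglutinin subunit, at -0.35 ± 0.07 (adjusted p of 0.0971), and a list adjusted p of 4.87e-05 and adjusted p = 0.326 with an estimated correlation. CBF5, GAR1, NHP2 and NOP10, the proteins of the box H/ACA particle that carries out guided pseudouridylation, had RNA log2 values of -0.10, -0.02, -0.12 and -0.19, none past the threshold. SUP35 and SUP45, the translation termination factors, were at 0.00 ± 0.06 and 0.00 ± 0.07 (SUP45 was at -0.0704 with library size only), NAM7, the helicase of nonsense-mediated decay, at 0.08 ± 0.07, and KRS1, the lysyl-tRNA synthetase, at 0.09 ± 0.07.

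The second comparison asked the same question of ribosome footprints. HIS4, ARG1 and the gene of the transcription factor Gcn4 were among the genes called higher. HIS4 went from 169 ± 9.77 to 329 ± 11.6 normalised footprint CPM (SD, n = 2), a log2 change of 0.96 ± 0.07, and ARG1 rose by 0.93 ± 0.07, both with an edgeR adjusted p of 9.00e-05. GCN4, the transcription factor itself, on chromosome 5 from 138918 to 139763 (R64), rose by 0.82 ± 0.12 in footprints (adjusted p of 0.00863), and its RNA had a log2 of 0.16 ± 0.07 with an adjusted p of 0.973. YGL117W rose by 0.95 ± 0.11, QDR3, a membrane transporter, by 0.78 ± 0.14, GCV1 by 0.77 ± 0.09, SNZ1 by 0.76 ± 0.08, GCV2 by 0.74 ± 0.09 and ARG7 by 0.72 ± 0.07. DESeq2 gave QDR3 no adjusted p (log2 0.77). Of 5461 genes tested, 32 were called higher and 0 lower, with 248 under an unadjusted p of 0.05 where 273 are expected by chance, while DESeq2 called 36 higher and 2 lower and limma-voom 32 higher and 0 lower. The count moved with single libraries: 53 without control replicate 1 (27 higher, 26 lower), 159 without targeted replicate 1 (103 higher, 56 lower) and 85 without targeted replicate 2 (62 higher, 23 lower), and it was 20 with library size as the only scaling, where QDR3 lost its call (0.78, adjusted p of 0.0591).

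In footprints 15 of the 46 Gcn4-list members were called higher, 46 of 46 lay above 0 and the median log2 was 0.33. The list adjusted p was 1.48e-92, and adjusted p = 0.104 with an estimated correlation. The lysine list had 2 called members, LYS20 at 0.46 ± 0.07 and LYS2 at 0.38 ± 0.07. Both lost the call without control replicate 2 (log2 0.43 and 0.32). LYS2 also lost it without control replicate 1 (0.44) and with library size only (0.37, edgeR adjusted p of 0.0675). The lysine list had an adjusted p of 7.63e-13, and adjusted p = 0.494 with an estimated correlation. Among the methionine genes HOM2 and MET13 rose by 0.44 ± 0.07 and 0.47 ± 0.09, with a list adjusted p of 2.63e-07 and adjusted p = 0.692 with an estimated correlation, while without control replicate 1 the list mean went from 0.17 to 0.0535 with an adjusted p of 0.364. HOM2 lost its call without control replicate 1 (0.42, adjusted p of 0.104) or 2 (0.45, 0.0868), and MET13 without control replicate 2 (0.41, 0.0810). The arginine and polyamine list (median 0.06) had 4.06e-09 and adjusted p = 0.494 with an estimated correlation, and the leucine and uracil list (median 0.11) had 0.000139 and adjusted p = 0.511 with an estimated correlation. Without Gcn4 members these were 0.901 and 0.259. MATa mating genes (median -0.07) had 0.00591 and adjusted p = 0.918 with an estimated correlation, and 0.300 without control replicate 1, where the mean went from -0.12 to -0.13. Ribosome biogenesis genes (median -0.04) had 0.0165 and adjusted p = 0.921 with an estimated correlation, 0.0986 without control replicate 2 (mean -0.0306 against -0.0417), and without targeted replicate 2 they were called in the opposite direction, with a mean of 0.0557 and an adjusted p of 0.00218. The 8 mitochondrially encoded genes had a median footprint log2 of -0.50, 7 of 8 below 0, with COX2, a subunit of cytochrome oxidase, at -0.81 ± 0.17 (adjusted p of 0.0761) and ATP6, of the ATP synthase, at -0.62 ± 0.21. The list adjusted p was 2.68e-08, and adjusted p = 0.692 with an estimated correlation, and 0.0879 without targeted replicate 1, where the mean went from -0.45 to -0.17. The reads behind it were few, from 901 to 1271 per library over the 8 genes.

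**Figure D1:**
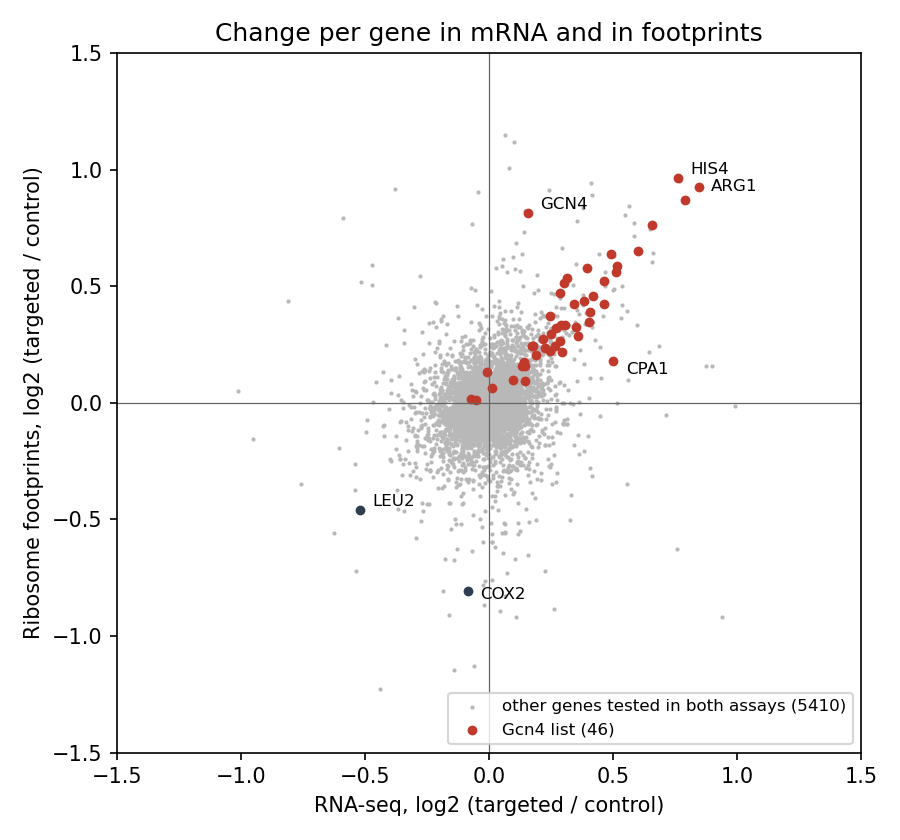
Each point is a gene tested in both assays, with the log2 ratio of targeted over control in RNA-seq on the x axis and in ribosome footprints on the y axis. Members of the Gcn4 list are red, LEU2 and COX2 dark, other genes grey, and 2 genes lie outside the axes. HIS4 and ARG1 lie at the upper right, and GCN4 lies at 0.16 in RNA and 0.82 in footprints.

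**Figure D2:**
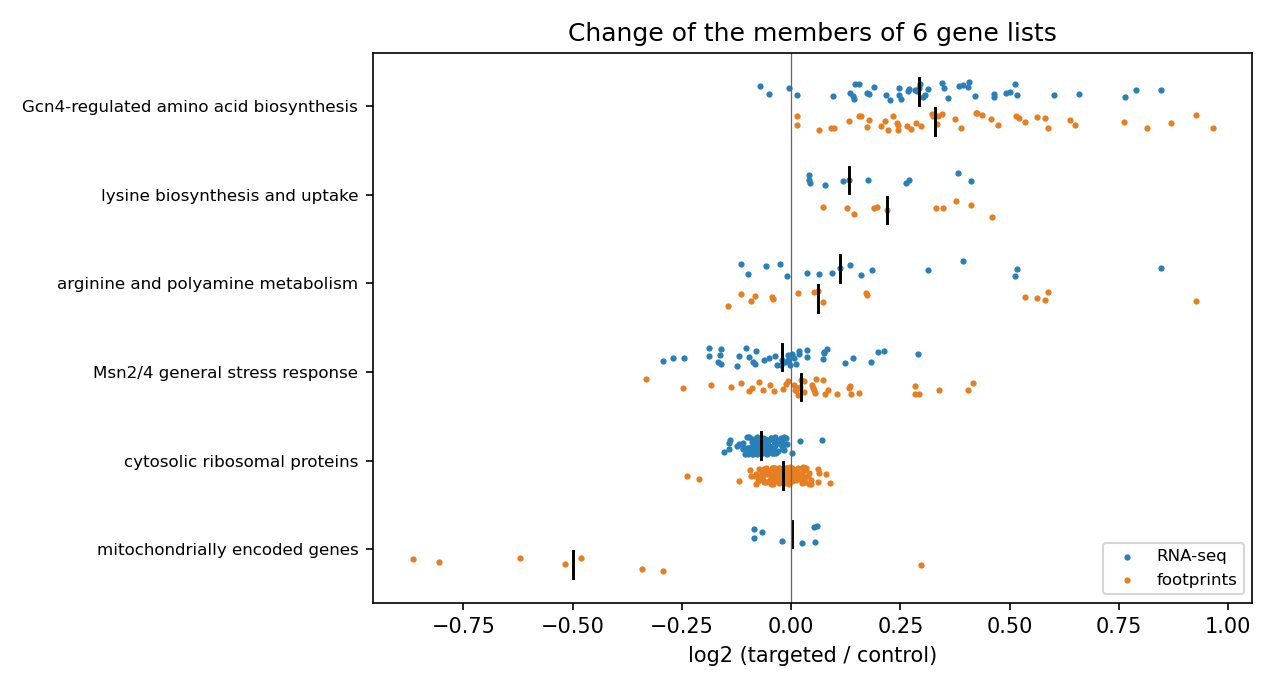
Log2 ratio of targeted over control (x axis) for each member of 6 gene lists, in RNA-seq (blue) and footprints (orange), with the median of each list as a black bar. The Gcn4 list has medians of 0.29 and 0.33, and the mitochondrially encoded genes have a footprint median of -0.50.

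Of the 21 genes called in RNA and the 32 called in footprints, 19 were shared. All 21 RNA calls lay above 0 in footprints. Across 5456 genes the log2 changes of RNA and footprints correlated with Pearson r of 0.289 and Spearman rho of 0.269, genes not being independent replicates, and r was 0.544 over the 3543 genes with at least 10 CPM in all 8 libraries. The RNA and footprint libraries came from the same lysates and share their deviations: the covariance of the changes was 0.00634, and 0.00806 is expected from the shared cultures alone. The correlation over all genes may therefore come entirely from the shared cultures, and the number of shared calls was not tested against it.

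The third comparison asked whether footprints changed beyond mRNA, that is, whether translational efficiency differed. GCN4 had the smallest p of 5665 genes, with a log2 ratio change of 0.66 ± 0.15 in the fit without a culture block, an unadjusted p of 0.00141 and an edgeR adjusted p of 0.999986. In that fit edgeR called 0 genes (51 higher and 54 lower under an unadjusted p of 0.05, where 283 in all are expected by chance), and DESeq2 and limma-voom called 0 as well, with 24 and 101 genes under an unadjusted p of 0.05. With the culture that gave both libraries as a block, a choice listed before the data were examined, edgeR called 6 genes: GCN4 higher by 0.67 ± 0.09 (adjusted p of 6.52e-05), and 5 mitochondrial rows lower, among them COX2 by -0.73 ± 0.12 (adjusted p of 0.00346) and COX1 by -0.58 ± 0.12 (adjusted p of 0.0310). The other 3, Q0255, AI4 and AI5_ALPHA, overlap COX2 or COX1 in their coordinates, so reads may be shared between these rows, which was not tested, and Q0255 held only 7 to 37 footprint reads per library. A lower ratio of the mitochondrial rows need not be lower translation, since capture of mitochondrial ribosomes was not tested. In this blocked fit 291 genes lay under an unadjusted p of 0.05, near the 283 expected by chance. In the authors' deposited table the translational efficiency of GCN4 is 0.203 and 0.243 in control cells and 0.348 and 0.367 in targeted cells.

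**Figure D3:**
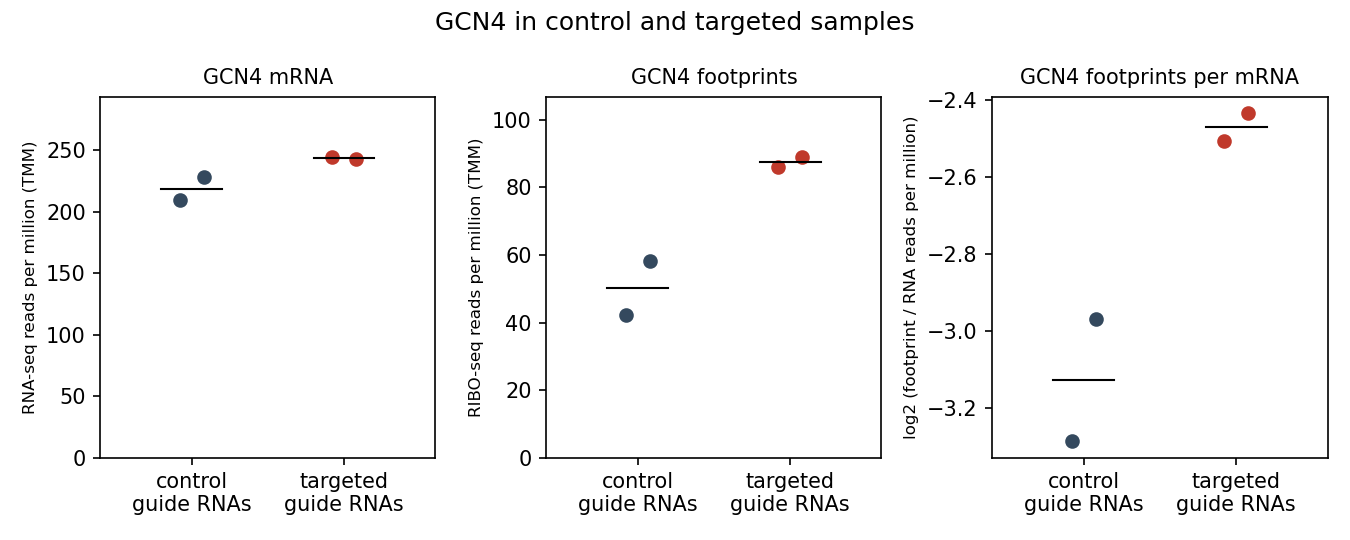
GCN4 in 2 control and 2 targeted samples, as normalised RNA-seq CPM (left), footprint CPM (middle) and the log2 ratio of footprint to RNA CPM (right). Points are libraries or pairs of libraries and bars are group means. Footprints were 42.3 and 58.1 in control cells and 86.0 and 89.1 in targeted cells, and the log2 ratio was -3.29 and -2.97 in control cells and -2.51 and -2.43 in targeted cells.

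The remaining genes named by the smallest p had values and no call. MEH1 was at 0.48 ± 0.13, NAT5 at 0.35 ± 0.11, QDR3 at 0.42 ± 0.14 and ECM31 at 0.47 ± 0.16, and CBP2, EMC6 and CDC5 were at -0.48 ± 0.13, -0.36 ± 0.11 and -0.27 ± 0.10. Without the block Q0255 and COX2 were at -1.93 ± 0.49 and -0.72 ± 0.20. As lists, the mitochondrially encoded genes were lower (mean log2 -0.44, adjusted p of 1.04e-08), the cytosolic ribosomal proteins higher (mean 0.05, adjusted p of 0.0156) and the Gcn4 list higher (mean 0.06, adjusted p of 0.0441). With an estimated correlation these were adjusted p = 0.888, 0.966 and 0.888. The sign of the ribosomal protein mean turned without targeted RNA replicate 2 (-0.0240) and without targeted footprint replicate 1 (-0.0224), and the list lost its call without control RNA replicate 2 (mean 0.0410, adjusted p of 0.258) and control footprint replicate 1 (0.0528, 0.138). The Gcn4 list lost its call without control RNA replicate 2 (mean 0.0410, adjusted p of 0.559), targeted RNA replicate 1 (0.0725, 0.0508), targeted RNA replicate 2 (0.0550, 0.170), control footprint replicate 1 (0.0409, 0.365) or targeted footprint replicate 1 (0.0482, 0.152), and the mitochondrial list had a mean of -0.15 and an adjusted p of 0.0851 without targeted footprint replicate 1. RLE scaling in place of TMM also ended the call of the Gcn4 list (mean 0.0522, adjusted p of 0.0731). With the culture block 5 lists passed, the further 2 being Msn2/4 stress genes (mean 0.08) and glycolysis (mean 0.04), each with an adjusted p of 0.0168. In the fit without the block neither passed (adjusted p of 0.353 and 0.295, and adjusted p = 0.966 with an estimated correlation for each), and the correlation was not estimated with the block.

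The last comparison set the baseline, footprints per mRNA in control cells. Histones, glycolytic enzymes and cytosolic ribosomal proteins carried more footprints per mRNA than the typical gene: 11 of 11 histone genes (median log2 1.15, HTB1 1.70 ± 0.04), 19 of 19 glycolytic genes (median 0.91, TDH1 1.75 ± 0.07) and 137 of 137 ribosomal protein genes (median 0.99, RPS29A 1.49 ± 0.04) were called higher. ANB1, an isoform of translation factor eIF5A, was the highest at 3.05 ± 0.07. How reads that map to several places were counted is not given. Values of close paralogs are thus uncertain, which bears on ANB1 and on gene copies within these lists. The 8 mitochondrially encoded genes were called lower with a median of -5.64, as were HAC1, the unfolded protein response factor whose unspliced mRNA is poorly translated, at -5.88 ± 0.11 and GCN4 at -3.15 ± 0.11. Whether footprints of mitochondrial ribosomes were captured was not tested, so the mitochondrial ratio need not reflect translation. Of the 14 reported targets of nonsense-mediated decay 11 were lower and 1 higher, with CPA1, which has an upstream reading frame, at -1.37 ± 0.08 and ALR1 at -1.19 ± 0.08. Of 5660 genes, 2067 were called higher and 2191 lower. With library size only, which moved the median of all genes to 0.95, the split was 4274 higher and 607 lower, and URA3 and NAM7 changed from -0.83 and -0.44 to 0.14 and 0.53. With an estimated correlation the smallest adjusted p of a list was adjusted p = 0.478. That setting could not pass even lists with every member called, so it is not evidence against them. The named genes with the lowest ratio, among them MTC7, FLO11 and DAN4, had 0 to 6 footprint reads per control library except AI2 (98 and 77 reads), so their fold changes rest on counts near 0 and are not given.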

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

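The tests of growth phase, of the spread of the mitochondrial median without 1 library, of the 3 explanations for reads outside the rows, and of GCN4 translation were chosen after the results were seen, and the others before. The list test of footprints beyond mRNA passed with the preset correlation for the mitochondrially encoded genes (mean log2 -0.44), the cytosolic ribosomal proteins (0.0491) and the Gcn4 list (0.0627). None passed with an estimated correlation (adjusted p = 0.888, 0.966 and 0.888 with an estimated correlation), and the ribosomal protein mean turned to -0.0240 without targeted RNA replicate 2 and -0.0224 without targeted footprint replicate 1. With the culture as a block the gene test passed for GCN4 (0.67), Q0255 (-1.94), COX2 (-0.73), COX1 (-0.58), AI4 (-0.80) and AI5_ALPHA (-0.62). RNA and footprints moved apart in every library for ECM31 (0.47), CBP2 (-0.48), EMC6 (-0.36) and CDC5 (-0.27), a difference without a test past the threshold.

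The higher values of the Gcn4 list in targeted cells were set against 2 technical explanations. A bias with coding length or expression does not reach it: the list mean was 0.32 in RNA, while the highest of 1000 random lists matched on both was 0.06. A later growth phase would raise the Msn2/4 stress genes, whose upper quartile in RNA was 0.0358, below the lower quartile of 0.18 of the Gcn4 list. That covers 1 list in RNA. Other growth-related lists differed: ribosomal proteins in RNA (mean -0.07), the stationary phase list in footprints (0.15) and Msn2/4 genes in the ratio with the culture block (0.08). The first 2 means changed sign with a library left out. The stationary phase list shares members with the Gcn4 list, and without them its mean was 0.08 and it no longer passed (camera adjusted p of 0.288). It therefore gives little separate support for a growth difference. A growth difference in the cultures thus stays open. So do the targeted guide RNAs as the biological explanation, with 2 samples per group, and other differences in culture such as amino acid supply. Neither the guide RNAs nor amino acid supply was tested.

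The lower footprints of mitochondrially encoded genes were set against 2 technical explanations. Less carry-over of RNA fragments would lower other genes with few footprints per mRNA, but the 100 nuclear genes with the fewest had a median of 0.0641 ± 0.0204 (bootstrap SE). This SE is over genes and holds no spread between libraries. Carry-over confined to mitochondrial RNA was not tested. The bound set before for a change made by 1 library, a median below -0.1 whichever library is left out, was met, with -0.26 ± 0.16 (bootstrap SE over members) without targeted footprint replicate 1. This stays open all the same, since that bound allowed for no spread and was passed by 1.05 SE where the carry-over test asked for 2, and since targeted replicate 2 (89.7 footprint CPM over the 8 genes) was about equal to control replicate 1 (91.0), with 59.1 and 121 in the others. Without targeted replicate 1 the list mean also went from -0.45 to -0.17 and the list test was no longer under 0.05 for footprints (adjusted p = 0.0879) or the ratio (0.0851), and mitochondrial ribosomes in the column eluate were not tested.

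Some reads enter the total behind the deposited RPKM values but no row of the table. Their share was 1.91 and 1.73% in targeted RNA libraries, against 0.577 and 0.665% in control, and 4.94 and 4.26% in targeted footprints, against 0.365 and 0.456%. Rounding of the RPKM values does not reach this, since the excess was at least 184 times the spread of the estimated total. The mean share in targeted footprints was 11.2-fold higher, a contrast chosen after the shares were seen. For 2 against 2 libraries the smallest possible two-sided permutation p is 0.333. The shares differed between these libraries, but a share of reads is not a level in the cell. A feature held at the same level in both groups is therefore not excluded. Reads of the reporter could give the higher shares, with a footprint-to-RNA ratio 3.83 times higher in targeted cells. Nothing in the table names the feature, so the reporter cannot be told apart from other features outside the rows.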

How the results depend on the processing

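The crossed block, the fits without transposon rows and the lists without Gcn4 members were added after seeing the data. RNA calls numbered 21, and 0 to 21 with a library left out, 13 without transposon rows, 19 with the number as a replicate block, and 71 with crossed numbers as a block. Footprint calls numbered 32, and 43 to 159 with a library left out, 20 with library size only, 60 with the number as a replicate block (39 crossed). Same-numbered control and targeted libraries deviated with r of -0.135 in RNA and -0.110 in footprints, so they share only a number. Calls of the ratio numbered 0, and 0 to 1 with a library left out, and 6 with the culture as a replicate block, 0 with the number. Baseline calls numbered 4258, and 3848 to 3966 with a library left out. List calls ranged with a library left out from 10 to 15 in RNA, 6 to 14 in footprints, 1 to 7 for the ratio and 15 to 18 at baseline, were 5 for the ratio with the culture as a replicate block, and were 0 in all 4 comparisons with the correlation estimated per list. Estimating the correlation leaves too few degrees of freedom for a list to pass easily, so that 0 is not evidence against any list. With the Gcn4 members taken out of every other list, 8 lists passed in RNA and 7 in footprints, the Gcn4 list among them, and the arginine and the leucine lists no longer passed. The Correlation of RNA and Ribo changes was 0.544585 over genes of at least 10 CPM in all 8 libraries with scaling factors from all genes, where the 0.544 of the results uses factors taken after the filter on low counts. Signs turned for SUP45 in RNA (-0.0704), URA3 (0.14) and NAM7 (0.53) at baseline with library size only. With a library left out, many values near 0 changed sign, and among the ranges that crossed 0 were those of the stationary phase list in footprints (-0.0263 to 0.354), cytosolic ribosomal proteins in RNA (-0.152 to 0.0119) and for the ratio (-0.0240 to 0.128), CBF5 in footprints (-0.13 to 0.0298), ribosome biogenesis in footprints (-0.152 to 0.0557) and NOP10 for the ratio (-0.0336 to 0.34). The cause was not tested. Fits with 1 library in a group assume that it varies like the others. Leaving out rows that are not protein coding removes none, so it was not run, nor were the stop codon and AAG lists or settings for normalised values.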

Other observations

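Lists outside amino acid synthesis also passed with the preset correlation and not with an estimated one. Footprints of glycolytic genes had a median log2 of 0.08 (list adjusted p of 0.00373, adjusted p = 0.921 with an estimated correlation, 0.0516 without control replicate 1 and 0.687 without targeted replicate 2, with means of 0.0797 and 0.0262 against 0.0858), with PDC6 at 0.33 ± 0.13 and ENO1 at 0.16 ± 0.08 and no member past the threshold. ADE17, of purine synthesis, was called narrowly in RNA (0.50 ± 0.08, adjusted p of 0.0495) and in footprints (0.49 ± 0.09, 0.0457), while its list was not called in either (adjusted p of 0.571 and 0.291). Its RNA call ended whichever of control replicate 1 (0.40, adjusted p of 0.652), targeted replicate 1 (0.50, 0.180) or targeted replicate 2 (0.51, 0.133) was left out, with RLE scaling (0.50, 0.0503), library size only (0.43, 0.0572) or all 8 libraries in 1 fit (0.50, 0.0515), and without transposon genes (0.51, 0.0643). Its footprint call ended without control replicate 1 (0.34, 0.155), with library size only (0.48, 0.138) and with all 8 libraries in 1 fit (0.49, 0.0540). IMD2, of guanine nucleotide synthesis, was at -0.32 ± 0.06 in RNA with an adjusted p of 0.0936. The stationary phase list passed in footprints (adjusted p of 0.00175, adjusted p = 0.692 with an estimated correlation, 0.903 without control replicate 1 with a mean of -0.0263 against 0.15), and its called member was SNZ1, which the Gcn4 list also holds; without Gcn4 members its mean was 0.08 and it no longer passed. Hsf1 chaperones, the proteasome, ergosterol synthesis, the iron regulon and the translation termination and decay factors were not called in RNA or footprints.

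CPA1, an enzyme subunit of arginine synthesis, was called at 0.50 ± 0.08 in RNA (adjusted p of 0.0422), and lost the call without control replicate 1 (0.41, 0.652), targeted replicate 1 (0.47, 0.171) or targeted replicate 2 (0.53, 0.0814) and without transposon genes (0.50, 0.0506), while its footprints were at 0.18 ± 0.10 (adjusted p of 0.999). Its ratio was at -0.32 ± 0.10 with the culture as a block, with an adjusted p of 0.516, and the log2 ratio was -1.30 and -1.39 in control cells and -1.62 and -1.72 in targeted cells.

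A hypothesis is that translation of GCN4 mRNA was raised in targeted cells. The log2 ratio was higher in both targeted samples, with a change of 0.66 and an adjusted p of 0.999986 in the fit without a block, and of 0.67 with an adjusted p of 6.52e-05 in the fit with the culture as a block, listed before the data were examined. The criterion, a pass in the fit without a block, was written when the result of that fit was already known, so it decides nothing. The fits differ in the call and hardly in the value, and with 2 samples per group the hypothesis stays open.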
